A study of Mus musculus with 5 samples.

How the data were processed

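Chromatin bound by RAP1 was immunoprecipitated and sequenced from mouse embryonic fibroblasts immortalised with the SV40 large T antigen. Per the labels, the series holds 5 libraries: 2 from wild-type fibroblasts, 2 from fibroblasts in which Rap1 was deleted, and 1 input without antibody. The design text names the Rap1-deleted lines as the negative control of the wild-type lines. Per the labels' protocols, nuclei were sonicated, the libraries were size-selected on a gel and amplified by PCR, and sequencing was done on the Illumina Genome Analyzer IIx.

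The values came from 1 deposited peak list for the whole series. Per the file headers, each peak has a rank, a position and columns for a positive and a negative set of reads, with no column for any single library. The positive set was read here as the wild-type libraries and the negative set as the Rap1-deleted libraries, following the design text; the file headers say only positive and negative. Whether the input entered the negative set, the aligner, the peak caller and the read filters were not given in the sources used here. The genome build was mm9, per the submitters' processing notes, and coordinates are printed as the deposited list gives them.

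Per the file headers, each peak carries the count of positive and negative reads over the whole peak, not normalised, and the highest number of reads in any window of the peak, a coverage signal in reads. It also carries the count of forward and reverse reads of each set in strand windows, which can reach beyond the peak. The deposited fold columns are log2 values. Solving them from the values gave log2 of (positive + 1) over (3.32 × negative + 1), and 140 of 141 solvable strand entries returned that factor within 0.001. For 30340 peaks (99.8%) the deposited log2 fold was the log2 of the highest positive window plus 1, within 0.001, so that it carries the positive reads alone. The deposited false discovery rate, a q-value, is the peak caller's own. A deposited column named Delta, from 0.0078 to 1, was not interpreted. Its lowest value is smaller than any ratio of positive strand-window reads, which run from 10 to 232 forward and 10 to 249 reverse. These per-peak scores are the authors' and served only to describe, rank and filter peaks.

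No total read number per library was used, so the depth of each library is unknown here, and the factor of 3.32 was the only scale between the read sets. Positive over scaled negative ratios have exact conditional binomial 95% intervals, and shares have exact Clopper-Pearson 95% intervals. Where a peak had no negative read in the whole-peak column or the strand windows, the ratio was bounded with a floor of 3 negative reads over the pooled set, which equals 9.96 positive reads after scaling. Intervals and floors cover counting error only, because PCR copies are not independent molecules and because every peak was selected on these same reads. With pooled reads, no value has a spread between replicates.

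Peaks per chromosome were compared with each chromosome's share of the summed length between its first and last listed peak, by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 20 chromosomes at 0.05. The 1 peak on chromosome Y was left out of tests. Peaks in the distal 2 Mb, measured from the last listed peak of each chromosome with that peak left out, were compared with 10000 circular shifts of the peaks within each chromosome, one-sided. The last listed peak stood in for the assembly end, since chromosome lengths of mm9 were not used here. Neighbour distances under 10 kb were compared with 1000 random placements within chromosomes, one-sided. Medians were compared by permutation tests with 100000 resamples, two-sided. Groups of peaks were joined at gaps of up to 10 kb.

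The tests described so far, apart from the groups of peaks, were fixed before the data were examined with their windows and a set of alternatives, as was the rule for naming peaks: the 20 best-ranked peaks and the 5 best-ranked in the distal 2 Mb. All other regions, the 5 largest groups of peaks among them, were chosen after their values were seen. The planned test between wild-type and Rap1-deleted libraries, its replicate block, and the comparison with input need values per library and were not run. Gene features, telomeric repeat content, the genes at peaks and 14 gene lists need the sequence or annotation of mm9, which was not used here, so no peak was assigned to a gene. A RefSeq gene table of the GRCm38 assembly served only to count protein-coding genes per chromosome. The alternatives were the better-ranked 50% or 10% of peaks, merging within 1 kb, other windows and distances, random placement, and leaving out each chromosome. Alternatives added after the data were seen were peaks without negative reads, permuted 1 Mb bins, windows that start at a listed peak, the proximal end, moving each peak by up to 500 kb, leaving out the largest group, reads centred on the chromosome median, means in place of medians with peak values rotated along each chromosome 10000 times, and strand windows in place of whole peaks. Other tests added then were the correlations across chromosomes, the 0.1 Mb window and its run without chromosomes 7, 11 and X, proximal windows without chromosome 11, the sign-flip test of distal against proximal windows, the share of peaks with 50 or more reads, and the read ratios of groups.

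The tests were checked on simulated lists of 30397 peaks, 20 lists each. A distal ratio of 1.51 was recovered as 1.502 on average and called in 20 of 20 lists, against 1 of 20 with no enrichment. Added neighbours were called in 20 of 20 lists, against 1 of 20 without. An even density gave 5 calls over all 20 lists of 20 chromosomes. Apart from the peaks added on purpose, simulated peaks were placed evenly at random within chromosomes. They lack the clustering of the real list, so these counts give no error rate for clustered peaks. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.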

Results

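RAP1 is a subunit of shelterin, the protein complex that covers telomeres, where it is held on the TTAGGG repeats by TRF2. The series asked where RAP1 sits along the genome of mouse embryonic fibroblasts immortalised with SV40 large T, a viral protein that blocks p53 and the retinoblastoma protein. It holds 2 wild-type immunoprecipitates, 2 from Rap1-deleted fibroblasts as the negative control, and 1 input. The deposited list pools the libraries into a positive and a negative read set, so there are no replicate values.

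The list holds 30398 RAP1 peaks on 21 chromosomes, spread over the interior of every autosome and X. The peaks are short, with a median of 56 bp (interquartile range 38 to 77 bp, full range 29 to 940 bp), and together cover 2286 kb. Of them, 5407 (17.8%) are only 29 to 31 bp long. The median peak holds 28 positive reads (interquartile range 24 to 34, full range 12 to 475), and every peak has at least 10 positive reads in the window of each strand. Few peaks rise far above the median: 1286 (4.23%) hold 50 or more positive reads and 27 hold 100 or more. The reverse-strand mode lay downstream of the forward-strand mode in 28268 peaks (93.0%), by a median of 52 bp over all peaks. The false discovery rate in the authors' deposited list runs from 3e-06 to 0.0860. It is at or under 0.01 for 16998 peaks and above 0.05 for 186.

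Set against the Rap1-deleted cells, most listed regions had no control reads in the deposited columns, and 18.8% had some. No negative read stands in any column for 24688 of the 30398 peaks. For these the median bound is at least 2.71-fold higher in the positive set, and for 24605 of them it is 2-fold or more. With no negative read, the bound is the positive reads of the peak over a constant floor. Every listed peak has at least 10 positive reads on each strand, so a bound of about 2-fold or more largely restates that minimum. The bounds therefore do not measure how far these peaks exceed the control. In the whole-peak column 30320 peaks (99.7%) have 0 negative reads, but 5632 of these have negative reads in the strand windows, so that 0 there is not taken as a bound. Of the 5707 peaks with negative strand reads, 3818 have a strand-window ratio under 2 and 2001 a ratio of 1 or less. Among those 5632 peaks, the highest negative window lay inside the peak for 51.9% of forward and 48.7% of reverse entries. The whole-peak negative column can thus miss reads inside a peak. Summed over the list, the whole-peak columns set 920616 positive against 199 negative reads, a scaled ratio of 1393 (95% interval 1212 to 1609). For that reason 1393 is not taken as the enrichment over the control. The strand windows set 914436 against 48131, a scaled ratio of 5.72 (5.67 to 5.77). Peaks were selected for an excess of positive reads, so these ratios describe the list and do not test binding. Whether the strand windows also miss negative reads was not tested, and every bound from 0 negative reads assumes that they do not.

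The 20 best-ranked peaks lie on 12 chromosomes, with 6 on chromosome 2, 3 on chromosome 11 and 2 on X. They hold 66 to 475 positive reads, and 6 of them have no negative read in either kind of column. The best-ranked, on chromosome 2 from 57482074 to 57482124, has 329 positive and 9 negative reads, 11.01-fold higher in the wild-type set (5.73 to 24.3), and a deposited log2 fold of 8.29. A 30 bp region on chromosome 8 from 73957000 to 73957029 has 244 positive and 0 negative reads, at least 24.5-fold higher, with no negative strand reads. The chromosome 4 peak from 31281392 to 31281422 has 160 against 8 reads, a ratio of 6.02 (2.98 to 14.2). On chromosome 2, the peak from 28040118 to 28040149 has 134 against 0 reads, at least 13.4-fold higher. These 3 peaks, ranked 2 to 4, are 30 to 32 bp long. The peaks ranked 7, 16 and 20 are 30 bp long and the one ranked 5 is 33 bp long. Stacks of PCR copies were not separated from binding for any peak. The most read-rich peak lies on X from 73844477 to 73844506, with 475 against 17 reads (8.41-fold, 5.20 to 14.6), and 4.53-fold (3.16 to 6.69) in the strand windows, from 32 negative reads. A second X peak just before it, from 73843980 to 73844188, has 225 against 11 reads (6.16-fold, 3.38 to 12.5). Over the 6 peaks without any negative read, bounds run from 7.53-fold to 24.5-fold. Another 4 have 0 negative reads over the peak and 5 to 11 in the strand windows, with strand ratios from 1.99 (1.02 to 4.34) on chromosome 16 from 17558235 to 17558295 to 4.58 (1.88 to 14.5) on chromosome 2 from 29627305 to 29627382. In the 10 peaks whose whole-peak negative count is 1 or more, ratios run from 6.02 to 38.2 over the peak and from 3.95 to 38.2 in the strand windows, the latter resting on 1 negative read (6.74 to 1522) on chromosome 11 from 51269148 to 51269216.

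**Figure D1:**
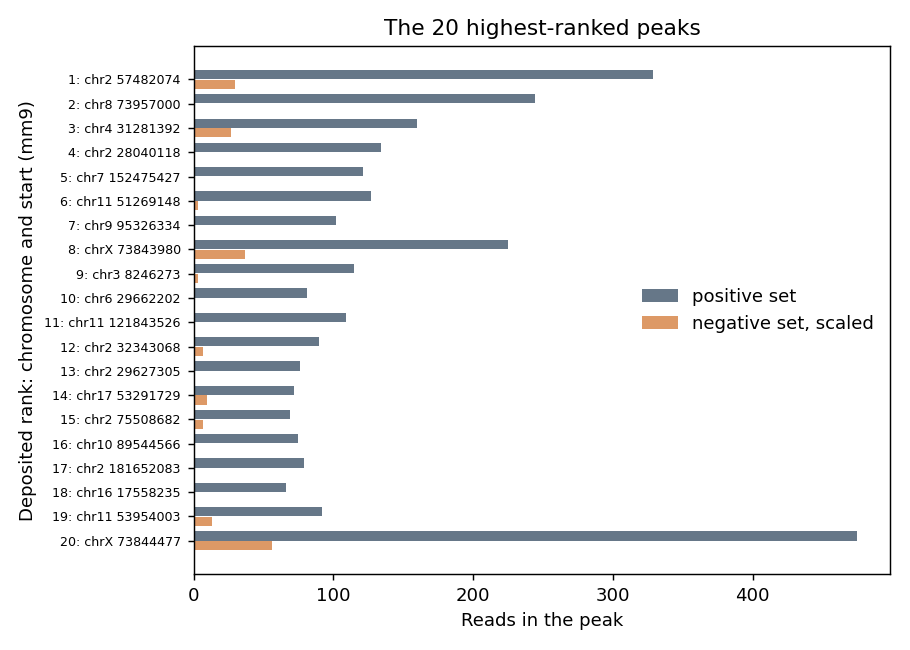
Reads in the 20 best-ranked peaks, named by rank, chromosome and start. Bars give whole-peak reads of the positive set and of the negative set scaled by 3.32. The whole-peak negative count can miss reads inside the peak, and pooled reads carry no error bar. The peaks hold 66 to 475 positive reads, 10 of them have 0 whole-peak negative reads, and 4 of these 10 have negative strand reads.

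RAP1 peaks were unevenly shared between chromosomes, with X poorest and chromosome 11 richest. X holds 2.84 peaks per Mb, 0.239 times the number expected from its length (0.218 to 0.262), against an autosome median of 12.3 per Mb. Chromosome 7 at 6.91 per Mb (0.583 times, 0.549 to 0.619) and chromosome 12 at 8.41 per Mb (0.710 times, 0.667 to 0.755) also lay below expectation. Chromosome 11 has 18.4 per Mb (1.56 times, 1.49 to 1.62), chromosome 19 has 17.5 (1.48 times, 1.39 to 1.57) and chromosome 15 has 15.9 (1.34 times, 1.28 to 1.41). In exact binomial tests 15 of 20 chromosomes differed from their share, 8 above and 7 below, with a largest adjusted p of 0.0347. The binomial test assumes an even rate along a chromosome, yet within chromosomes the variance of 1 Mb bin counts is 2.58 to 10.1 times their mean (median 5.41). The intervals given here rest on the same assumption and are too narrow for such uneven counts. Permuting whole bins among chromosomes, a test added after the data were seen, left 9 calls, 6 above and 3 below, all 9 in the same direction as before and the 6 chromosomes named here among them.

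In correlations added after the data were seen, peak density across the 20 chromosomes rose with the positive reads per peak and with the share of peaks that have negative strand reads. Between peaks per Mb and mean positive reads per peak, Pearson's r was 0.813 and Spearman's rho 0.886, each with a permutation p of 1e-05, the smallest it can give, and an adjusted p of 3e-05. Without chromosomes 12 and 11, r was 0.770. For the share of peaks with negative strand reads, r was 0.733 (permutation p = 0.00024, adjusted 0.00036) and rho 0.782 (p = 0.0001, adjusted 0.00015), and without chromosomes 17 and 11 r was 0.694. For protein-coding genes per Mb, rho was 0.451 (permutation p = 0.0465, adjusted 0.0465 over the 3 relations) and r was 0.384 (p = 0.0935, adjusted 0.0935). Without chromosomes 11 and 7, that r was 0.580. Chromosome 7 stood apart, with 13.6 protein-coding genes per Mb and 6.91 peaks per Mb, whereas chromosome 11 has 13.5 genes and 18.4 peaks per Mb.

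**Figure D2:**
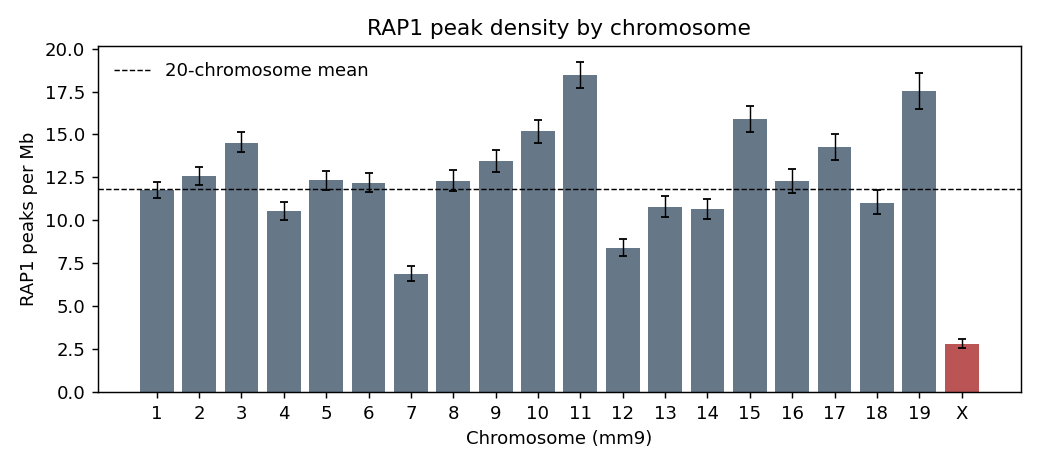
RAP1 peaks per Mb on each chromosome between its first and last listed peak, with exact binomial 95% intervals as bars and the mean of the 20 chromosomes as a dashed line. The intervals assume an even rate along a chromosome and are too narrow for unevenly spread peaks. X stands at 2.84 peaks per Mb and chromosome 11 at 18.4.

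Peaks were denser towards the distal chromosome ends, the ends away from the centromere in these telocentric chromosomes. The distal 2 Mb of the 20 chromosomes hold 730 peaks where 488 were expected, a ratio of 1.497 (one-sided circular-shift permutation p = 0.0005), and 16 of 20 chromosomes lay above expectation. The ratio rose towards the end, from 1.30 in the distal 5 Mb (permutation p = 0.0023) to 1.74 in 1 Mb and 2.04 in 0.5 Mb (both p = 0.0001, the smallest 10000 shifts can give). In the last 0.1 Mb, a window added after the data were seen, 69 peaks stood against 24.4 expected, a ratio of 2.83 (permutation p = 0.0008). Chromosome 7 with 11, X with 10 and chromosome 11 with 7 gave many of these, and the other 17 chromosomes have 41 against 21.6 (1.90, permutation p = 0.0051). On single chromosomes the 2 Mb ratio was 3.18 on X, 2.97 on chromosome 7, 2.52 on chromosome 15 and 2.03 on chromosome 11, against 0.456 on chromosome 17 and 0.589 on chromosome 18. The X value rests on 18 peaks against 5.66 expected. Of these 18, 8 form 1 group in which 7 peaks have negative strand reads and the strand ratio is 1.54 (1.204 to 1.98).

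The proximal 2 Mb hold 562 peaks against 488 expected, a ratio of 1.15 (permutation p = 0.12), and 0.934 without chromosome 11 (p = 0.696). In a test added after the data were seen, the distal windows hold 168 more peaks than the proximal ones, a difference not past the threshold over 20 chromosomes (two-sided sign-flip permutation p = 0.195, distal higher on 13, proximal higher on 6). Without chromosome 11, whose proximal end holds a dense group of peaks, the difference is 234 (permutation p = 0.0207). Closer in, the proximal ratio was 1.57 in 0.5 Mb (permutation p = 0.006, 11 of 20 chromosomes above expectation) and 3.90 in 0.1 Mb (permutation p = 0.0003). Without that chromosome these fall to 0.923 (permutation p = 0.662) and 1.02 (permutation p = 0.479).

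**Figure D3:**
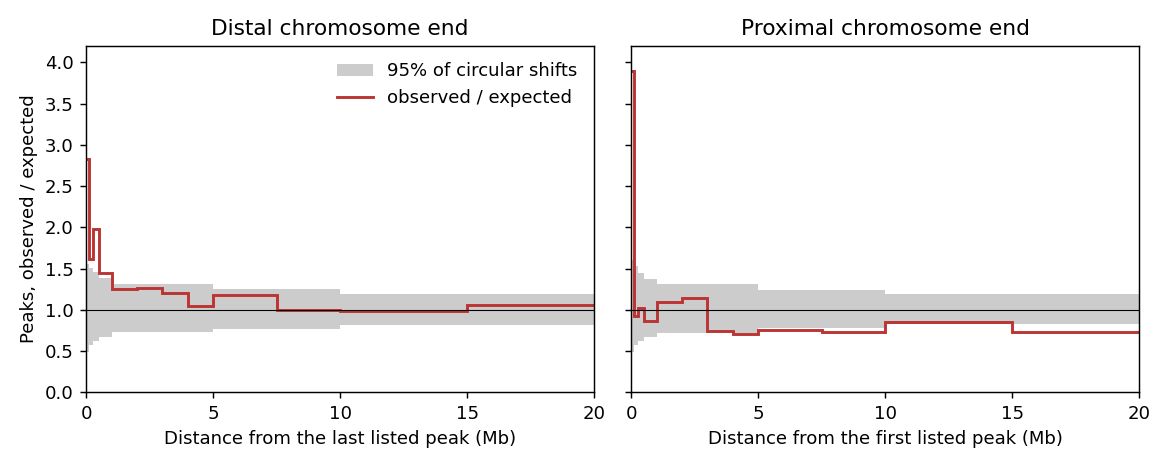
Observed over expected RAP1 peaks by distance in Mb from the last (left) or first (right) listed peak, over 20 chromosomes, with the grey band holding 95% of circular shifts. The distal line starts at 2.83 and enters the band beyond 1 Mb. The first proximal bin, at 3.90, is mostly the group on chromosome 11. Farther in, the proximal line lies below the band from 4 to 10 Mb (0.702 to 0.750) and from 15 to 20 Mb (0.726).

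The best-ranked distal peak lies on chromosome 7 from 152475427 to 152475459, 41.2 kb before the last listed peak end, with 121 positive and 0 negative reads over the peak. Its strand windows hold 11 negative reads and give a ratio of 3.04 (1.63 to 6.26). The last peak of chromosome 11, from 121843526 to 121843788, has 109 against 0 reads (at least 10.9-fold) and no negative strand reads. The other 3 of the distal 5 are on chromosome 2 from 181652083 to 181652137 (79 against 0 whole-peak reads, strand ratio 4.34 from 5 negative reads), chromosome 17 from 93557912 to 93557961 (59 against 2) and chromosome 7 from 152479821 to 152479940 (105 against 0, strand ratio 10.5 from 3). Distal peaks included a larger share with many positive reads, while no difference in deposited fold was detected. For 99.8% of peaks that fold carries positive reads alone, so neither measure sets distal peaks against the control. Of the 750 distal peaks 60 (8.0%, 6.16 to 10.2) hold 50 or more positive reads, against 1226 of the 29647 others (4.14%, 3.91 to 4.37). Rotating the peak values along each chromosome, which keeps neighbouring peaks together, gave a two-sided permutation p of 0.0162 for that difference; the minimum of 50 and this test were chosen after the data were seen. The mean was 32.1 positive reads in distal and 30.2 in other peaks (rotation permutation p = 0.0156). The mean deposited log2 fold was 4.76 against 4.74 (rotation permutation p = 0.19). The summed strand ratio was 5.11 in distal and 5.74 in other peaks (rotation permutation p = 0.484), and negative strand reads stood at 22.4% against 18.7% of peaks (rotation permutation p = 0.153), so neither difference passed. The median deposited log2 fold is 4.70 in both classes (difference 0, permutation p = 1), but medians of small whole read numbers tie and that test could hardly show a difference.

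RAP1 peaks lay closer together than random placement gives. Of 30377 neighbouring pairs, 6121 (20.2%) are under 10 kb apart, against 12.04% with peaks placed evenly at random, a ratio of 1.67 (one-sided permutation p = 0.001, the smallest 1000 placements can give). The ratio was 2.47 under 1 kb and 1.07 under 100 kb. Joined at 10 kb, the peaks form 24256 groups, of which 19868 are single peaks and 113 hold 5 or more.

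The largest group lies at the proximal end of chromosome 11, from 3025355 to 3100104, with 72 peaks. Its strand windows hold 3701 positive and 984 negative reads, a ratio of 1.13 (1.06 to 1.22), and 66 of its peaks have negative strand reads. The next 4 groups reach higher ratios. On chromosome 11 from 86384389 to 86407280, 12 peaks give 2.21 (1.73 to 2.86). On chromosome 9 from 41398121 to 41412216, 11 peaks give 2.73 (2.04 to 3.74). On chromosome 5 from 143659144 to 143677942, 11 peaks give 1.82 (1.42 to 2.37). On chromosome 1 from 164114291 to 164155239, 11 peaks give 24.7 (10.5 to 76.4). Over the 113 groups, 65 have a ratio above 2 with its whole interval or no negative strand reads, 11 have an interval wholly under 2 and 37 span 2. Of the 65, 17 have no negative strand reads, the largest being 7 peaks on chromosome 16 from 55952185 to 55976404 with 212 positive strand reads.

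**Figure D4:**
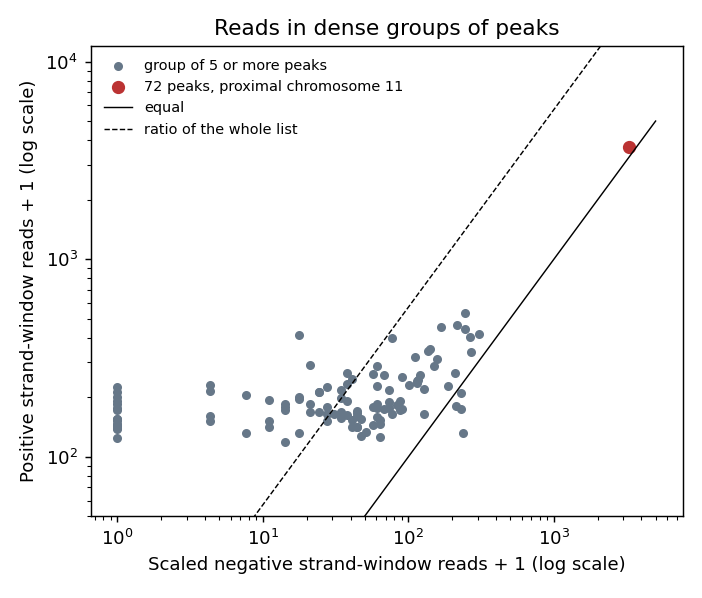
Positive against scaled negative strand-window reads, each plus 1, on log axes, for the 113 groups of 5 or more peaks (points). Lines mark equality and the whole-list ratio of 5.72. The group of 72 peaks on chromosome 11 lies near equality, at 1.13.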

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

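The distal ratio among peaks without negative reads and the thinning test for X were chosen after the list had been seen but before their own results; the other tests in this part were chosen after their results were seen.

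Negative reads appeared in columns that the peak-level comparison does not use. In 5632 peaks with 0 negative reads over the whole peak, the strand windows hold at least 1. The highest negative window lay inside the peak for 1616 of 3112 such forward entries (51.9%) and for 1526 of 3135 reverse entries (48.7%). In 135 peaks a deposited log2 fold on a single strand is under 0, more scaled negative than positive reads at the position of the largest absolute fold. Over the summed strand windows, 2001 peaks have a ratio of 1 or less. On chromosome 8 from 73389698 to 73404789 a group of 5 peaks has a strand ratio of 0.556 (0.413 to 0.752).

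The group of 72 peaks at the proximal end of chromosome 11 had nearly as many scaled negative as positive reads. Its ratio of 1.13 (1.06 to 1.22) lies under the 5.72 of the whole list, as reads from extra copies of the sequence, present in both read sets, would give. It stands out less against the median of 3.29 over the 96 groups of 5 or more peaks with negative strand reads. Of these 96, 5 lie at or under its ratio, the group itself included. The median over the 5707 peaks with such reads is 1.33. Candidate explanations of that kind are a repeat that is collapsed in the assembly or a gain of the region in the cells; these were not separated. The small excess over 1 also leaves some Rap1-dependent signal open.

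Peak density differed between chromosomes by 2.67-fold over autosomes, and X stood at 22.8% of the autosomal density. Density followed mean reads per peak (rho 0.886), so a different read depth per chromosome against a fixed read minimum may contribute; it also followed gene density by rank (rho 0.451, permutation p = 0.0465), though not by Pearson's r (0.384, permutation p = 0.0935), and both stay open. Thinning autosomal reads to 50% kept 7.45% of autosomal peaks (SD 0.122 over 100 draws), fewer than X holds. This holds for X at exactly 50% of autosomal depth, with autosomal site density and the minimum of 10 reads per strand as the only rule. Thinning to 60% kept 16.1% and to 70% kept 29.1%, and X at 22.8% lies between these. A lower depth of X than of autosomes therefore stays open as a reason for its few peaks. The copy number of X and of the autosomes was not in the labels.

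The higher density near the distal ends held among the peaks without any negative read (2 Mb ratio 1.43, permutation p = 0.0003), which argues against control reads as its only source. In the last 0.1 Mb, a window added after the data were seen, the ratio was 2.83 with all 69 peaks. Among peaks without any negative read it was 2.13 with 42 peaks (permutation p = 0.0005). The rise at the very end was thus smaller without the peaks that have negative reads. The higher density was seen on 16 of 20 chromosomes, which argues against a few chromosomes alone. Against windows that also start at a listed peak the ratio was 1.45 (permutation p = 0.0008), which argues against the clustering of peaks alone. Gene density, sequence content and the mappability of the ends were not tested and stay open. A telomere-linked enrichment in wild-type cells is a hypothesis that these tests leave standing, although the distal excess over the proximal ends missed its threshold over 20 chromosomes (sign-flip permutation p = 0.195).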

How the results depend on the processing

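Of the tests in this part, those of peaks without negative reads, permuted bins, proximal ends, windows starting at a listed peak, moved peaks, the left-out group, centred reads, means and strand windows were chosen after the data were seen. Permuting 1 Mb bins moved the called chromosomes from 15 to 9, because bins carry the uneven spread of peaks; the 3 other alternatives gave 12 to 14. The distal ratio passed its threshold under 28 alternatives. Leaving out each chromosome gave 1.43 to 1.56, with p of at most 0.0025. The proximal end in place of the distal end gave 1.15 and did not pass (permutation p = 0.12); the cause was not tested. Clustering passed under all 6 alternatives, from 1.07 at 100 kb to 2.47 at 1 kb, and gave 1.28 with each peak moved by up to 500 kb (permutation p = 0.005, the smallest 200 draws can give). The median strength of distal and other peaks differed by 0 under 5 alternatives, which says little since medians of small read numbers tie. The mean number of positive reads, with values rotated along the chromosomes, was 1.84 higher in distal peaks (permutation p = 0.0156), and the mean log2 fold 0.02 higher (permutation p = 0.19). Strand windows in place of whole peaks moved the ratio of the list from 1393 to 5.72. Negative reads were 199 in the whole-peak column and 48131 in the strand windows. Why the whole-peak column holds so few was not tested.

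No paired analysis was possible because the list pools the libraries and carries no replicate numbers. For the same reason leaving out single libraries, other normalizations, count filters, pseudocounts and the fit with input were not run. The settings set aside for gene features, telomeric repeats, genes with a peak and gene lists were not run, since mm9 sequence and annotation were not used here. Depth limits single peaks: for the peaks without any negative read the median bound is at least 2.71-fold. That bound follows from their positive reads and the fixed floor alone.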

Other observations

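The tests in this part were chosen after the data were seen.

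Some groups of 5 or more peaks lay near chromosome ends. Within 2 Mb of the last listed peak lie 9 such groups, and within 2 Mb of the first lie 3. A pair of groups lies near the end of chromosome 7, the nearer one 30.97 kb before the last listed peak end: 5 peaks from 152422769 to 152452393 with a strand ratio of 4.80 (2.98 to 8.22) and 5 peaks from 152470193 to 152485666 with 5.22 (3.43 to 8.34). On chromosome 15 the 5 peaks from 103016109 to 103046554 have 224 positive and no negative strand reads. The 3 distal groups with the highest measured ratios have 5 peaks each: 19.7 (5.35 to 164.6) on chromosome 11 from 120424107 to 120438707, 12.9 (4.97 to 48.1) on chromosome 10 from 128182258 to 128203797, and 6.66 (3.31 to 15.7) on chromosome 15 from 102492572 to 102505676. The 3 with the lowest have 1.54 (1.204 to 1.98) for the 8 peaks near the end of X from 166407873 to 166421840, 1.93 (1.28 to 3.01) for 6 peaks on chromosome 5 from 151990155 to 152015551, and 2.19 (1.44 to 3.48) for 5 peaks on chromosome 15 from 101930098 to 101947465. All 3 groups near the first listed peak have ratios under 2 with their whole interval: the 72 peaks on chromosome 11, 7 peaks on chromosome 18 from 3004948 to 3010534 (1.37, 1.09 to 1.74), and 6 peaks on chromosome 19 from 4309897 to 4316424 (0.842, 0.630 to 1.14). The balance of distal and proximal groups was not compared by a test.

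Dense stretches were also found inside chromosomes. The median 1 Mb bin holds 10 peaks, 82 of 2582 bins hold none, and 18 hold 40 or more. After the bin of the chromosome 11 group, with 108 peaks, the fullest bins are on chromosome 19 from 5000000 to 5999999 with 66 peaks, chromosome 3 from 95000000 to 95999999 with 57 and chromosome 11 from 86000000 to 86999999 with 52. Within the first of these, 10 peaks from 5786593 to 5804345 have a strand ratio of 2.15 (1.66 to 2.83) and 9 peaks from 5835981 to 5851585 one of 2.50 (1.81 to 3.55).

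The larger share of distal peaks with 50 or more reads passed the rotation test when any chromosome was left out, with a largest permutation p of 0.0231. The peak on chromosome 7 from 152439141 to 152439172 has 149 positive reads, among the 10 highest counts, yet rank 22199, with 9 negative reads and a strand ratio of 2.77 (1.62 to 5.08).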
